A study of Mus musculus with 3 samples.

How the data were processed

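Wounds of 5 mm were made through the full thickness of the dorsal skin of female C57BL/6J mice at postnatal day 50 and held open with splints. They were left untreated or given 20 µL of gelatin methacryloyl, crosslinked with ultraviolet light for 1 min, without or with apoptotic neutrophils. Tissue was taken 5 days later with a margin of 2 mm, fixed for 24 h and dissociated with Liberase at 5 mg/mL for 2 h at 37 °C. Libraries were made with the 10x Genomics Flex chemistry, in which probe pairs bind transcripts in fixed cells, and sequenced on a NovaSeq X. The data are 1 library per group: the untreated wound, GelMA, and GelMA with apoptotic neutrophils (AN-GelMA). The labels do not say how many mice went into a library, so the animal, the piece of skin and the treatment move together. No paired analysis was possible because each group has 1 library and every library is numbered replicate 1. The group of the AN-GelMA library was taken from its labels, while its files carry the word heat; what that word stands for, and how the neutrophils were made apoptotic, is not given in the sources used here. The values of that library, those of heat shock genes among them, are to be read with this in mind.

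The deposited matrices hold counts, that is, UMI counts per gene and cell barcode, made by the authors with Cell Ranger (10.0.0 per the file headers) on the mouse builds GRCm39 and mm39 named in the submitters' processing notes. Values were checked to be whole numbers, with the same 19070 features in each library; 10 features share 5 symbols and were kept apart by Ensembl identifier. The probe set version and the settings used to call cells are not given in the sources used here. The reference annotation at hand is of another build, so no coordinates were used. A gene without a probe cannot be seen, which left Ly6c2, Cx3cr1, Aldoa, Eno1, Gapdh, Mx1 and Mx2 out of the lists.

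The untreated, GelMA and AN-GelMA libraries held 6073, 11449 and 9648 barcodes and 8945496, 21613482 and 14156692 UMIs, with medians of 1125, 1485 and 1134 UMIs and 851, 1046 and 848 genes per barcode. Cells with at least 400 UMIs, at least 250 genes and at most 10% mitochondrial UMIs were kept. The UMI minimum removed none, since the lowest barcode had 487; the filter removed 34, 147 and 36 cells. Scrublet, run per library through Scanpy, set thresholds of 0.564, 0.636 and 0.624 that called 0 doublets, so it did not separate them here; the 5% of cells with the highest score in each library were removed in its place (318, 615 and 518), a choice made after this was seen. This left 5721, 10687 and 9094 cells, 25502 in all.

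Counts were scaled to 10000 per cell and logged. The 2000 most variable genes were scaled to a maximum of 10 and reduced to 30 principal components. A graph of 15 neighbours was divided with the Leiden method at resolution 1, without integration between libraries. Clusters were named from 16 sets of markers fixed before the data were examined, as were the gene lists, the comparisons, the rule for named genes and the first 12 alternatives below. The naming rule itself took several forms after the cluster tables with cells per library were seen, and before any list or gene comparison was looked at. A cluster was named for its best class when the mean log2 level of markers over the 25th percentile of clusters was at least 1.8 and at least 0.5 above the next class, with at least 3 markers. Among its 10 leading genes no other class could have more markers than the best class, which left 2 clusters unnamed that met the other limits. A marker counted at 4 times that level and 50 CPM. Mixed clusters were divided once more at resolution 0.5, and clusters under 50 cells stayed unnamed, a limit set after a cluster of 18 cells, 16 of them untreated, was seen to enter the neutrophils. Class names mean cells like that class by these markers. Hair-forming clusters fell below the score except a hair shaft cluster, which stayed with the keratinocytes.

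For each class and library the counts were summed and divided by their total, giving CPM, the usual share-of-total scale for counts. The macrophage sums were 751832, 350176 and 1592303 UMIs for the untreated, GelMA and AN-GelMA libraries, so 1 UMI is 1.33, 2.86 and 0.628 CPM; fibroblasts had 1275580, 685637 and 2429844, endothelial cells 434441, 397223 and 382513, keratinocytes 4213306, 10336683 and 7015841 and neutrophils 41187, 122400 and 96092. A class was compared where both libraries held at least 50 cells, in AN-GelMA over GelMA, GelMA over untreated and AN-GelMA over untreated, which share libraries and are not independent. Results are log2 CPM ratios with exact counting intervals. A gene is called higher or lower at a ratio of 1.5 or more either way, and 0 counts are taken as 3 UMIs and give a bound. With 1 library per group no test, p-value or count of changed genes is given, since cells are not replicates.

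There were 22 fixed gene lists, 12 of them for macrophages. For a list, the median log2 ratio of members with at least 20 UMIs over both libraries is given with a 95% interval from 1000 Poisson draws of the counts. Its percentile is taken among 10000 random lists of the same size drawn within 20 bins of expression, and a list is called outside the random range below 2.5 or above 97.5. Of 96 list medians, 60 were called. The percentile compares genes within a pair of libraries and says nothing about other animals. Named genes are the 10 highest and 10 lowest in macrophages, and the 4 highest and 4 lowest in other classes, among genes with at least 100 UMIs in the higher library. Their CPM there must also be at least 0.5 of that in any other class (the leak filter, for RNA released by other cells), and mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes were left out. The 4 members of each list with the largest ratio and 8 genes chosen beforehand (Vegfa, Il1b, Tnf, Arg1, Mrc1, Mertk, Nos2 and Il10) were also named, and the text gives a part of the list members. Some genes that meet these rules are not reported here.

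The first 12 alternatives were at least 1000 UMIs per cell, no filter on cells, doublets kept, Leiden resolution 0.5 and 2, a class per cell, TMM factors of edgeR, the mean of per-cell CPM, cells thinned to 500 UMIs with equal cell numbers, and list members with at least 100 UMIs, at least 1 UMI or passing the leak filter. Others, added after the data were seen, took single clusters out or alone, named small clusters, counted hair-forming clusters as keratinocytes, or left hair-forming, unnamed, muscle and pigment cells out of the shares. TMM shifted all macrophage log2 ratios by 0.22, -0.15 and 0.068 and all fibroblast ratios by 0.17, -0.11 and 0.059 for the 3 comparisons in the order above, and neutrophil ratios by 0.10. Endothelial and keratinocyte ratios shifted by at most 0.067 either way. The calculation was tested on simulated AN-GelMA over GelMA macrophage sums, in which 8994 genes had at least 20 UMIs over both libraries. Known folds were planted in 200 genes with at least 100 UMIs over both libraries, with Poisson counting noise alone. All planted genes had the right direction; 50.0% of those planted at 1.5-fold, 95.5% at 2-fold and 100% at 4-fold passed 1.5, as did 3.66% of unchanged genes. A list of 20 genes planted at 2-fold gave a median of 0.89 at percentile 100, and 5% of 100 unchanged lists fell outside the random range. The unchanged lists were drawn at random from genes simulated independently, so a share near 5% was built in. It gives no rate of false calls for lists of genes that move together. The lists and the unchanged genes were also taken from genes of at least 100 UMIs. Rates for list members between 20 and 100 UMIs, and under variation between animals, were not measured.

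Versions were Python 3.11.15, Scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9, edgeR 4.0.16 and R 4.3.3. Random seeds were fixed at 0, except for the simulated data, which used other fixed seeds. Clusters without a class were left out of the gene comparisons, as were dendritic cells, T cells and other classes outside the 5 compared.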

Results

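Full-thickness skin wounds of female C57BL/6J mice were taken 5 days after wounding. They had been left untreated, covered with a gelatin methacryloyl hydrogel (GelMA), or covered with the same gel loaded with apoptotic neutrophils (AN-GelMA). Fixed cells were profiled with a probe-based single-cell RNA assay, 1 library per group. AN-GelMA against GelMA addresses what the apoptotic cargo adds to the gel, GelMA against the untreated wound what the gel does alone, and AN-GelMA against the untreated wound the whole treatment. No test between groups is possible with 1 library each, and 95% intervals, in brackets, cover counting error only. Cell classes rest on marker genes, and "macrophages" stands for monocyte- or macrophage-like cells, with the other class names used in the same way.

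Macrophages and fibroblasts, the cells that clear debris and rebuild matrix in a wound, took a smaller share of the GelMA library than of the other two. Macrophages were 652 of 5721 cells in the untreated library, 390 of 10687 in GelMA and 1535 of 9094 in AN-GelMA, or 11.4% (10.6 to 12.2), 3.65% (3.30 to 4.02) and 16.9% (16.1 to 17.7). Fibroblasts were 18.5% (17.5 to 19.6), 6.07% (5.63 to 6.54) and 22.2% (21.4 to 23.1), in the same order. Neutrophils, the first leukocytes to reach a wound, were scarce in all 3 libraries at 0.682% (0.485 to 0.931), 0.889% (0.720 to 1.09) and 1.06% (0.856 to 1.29). Blood endothelial cells were 6.85%, 3.98% and 3.91%, and keratinocytes 40.2%, 45.3% and 43.2%. Skeletal muscle cells, which in mouse skin form a thin sheet below the fat, were 3.04%, 7.59% and 1.83%.

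Cells that build hair accounted for much of the GelMA library. The 6 clusters led by hair matrix, inner root sheath and hair shaft genes (Krt35, Lef1, Krt71, Tchh, Krt81) held 3.92%, 27.3% and 0.737% of the untreated, GelMA and AN-GelMA cells. A minimum marker score set after the clusters were seen left 5 of them without a class (3.83%, 24.6% and 0.737%), while the hair shaft cluster stayed with the keratinocytes (0.0874%, 2.66% and 0%). An outer root sheath type cluster led by Tbx1 and Krt75, counted with the keratinocytes, held 2.62%, 14.7% and 1.06%. A cluster of the upper follicle (Krt79, Gata6) held 5.02%, 2.81% and 6.05%. With hair-forming, unnamed, muscle and pigment cells left out, macrophages were 13.1%, 5.84% and 17.9% and fibroblasts 21.3%, 9.72% and 23.6% of the remaining cells.

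Among cells of the named immune classes alone, macrophages were 76.7%, 61.2% and 79.6% in the untreated, GelMA and AN-GelMA libraries. Clusters without a class are not in this denominator. Among them are a cluster led by H2-M5 and Cd207 (105, 110 and 81 cells) and one led by Siglech (11, 11 and 39). With these counted as immune cells the macrophage shares would be lower in each library. Neutrophils were 4.59%, 14.9% and 4.98%, T, NK or innate lymphoid cells 10.9%, 16.6% and 8.35%, and dendritic cells 7.76%, 7.22% and 7.10%. Of all cells, the immune classes together were 14.9%, 5.96% and 21.2%, dendritic cells 1.15%, 0.430% and 1.51% and T, NK or innate lymphoid cells 1.63%, 0.992% and 1.77%. Macrophages per fibroblast were 0.615, 0.601 and 0.759, and macrophages per endothelial cell 1.66, 0.918 and 4.31. Pericytes or smooth muscle were 1.8%, 0.954% and 0.748%, Schwann cells 1.43%, 0.655% and 0.451%, melanocytes 0.454%, 0.786% and 0.352%, adipocytes or sebocytes 3.44%, 2.29% and 2.69%, and unnamed clusters 9.33%, 26.5% and 3.40%. The adipocyte or sebocyte class pools clusters that differ in order. A cluster led by Plin1 and Cidec held 0.454%, 0.664% and 0.253% of cells, and a cluster led by Far2 and Scd1 2.99%, 1.63% and 2.44%.

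**Figure D1:**
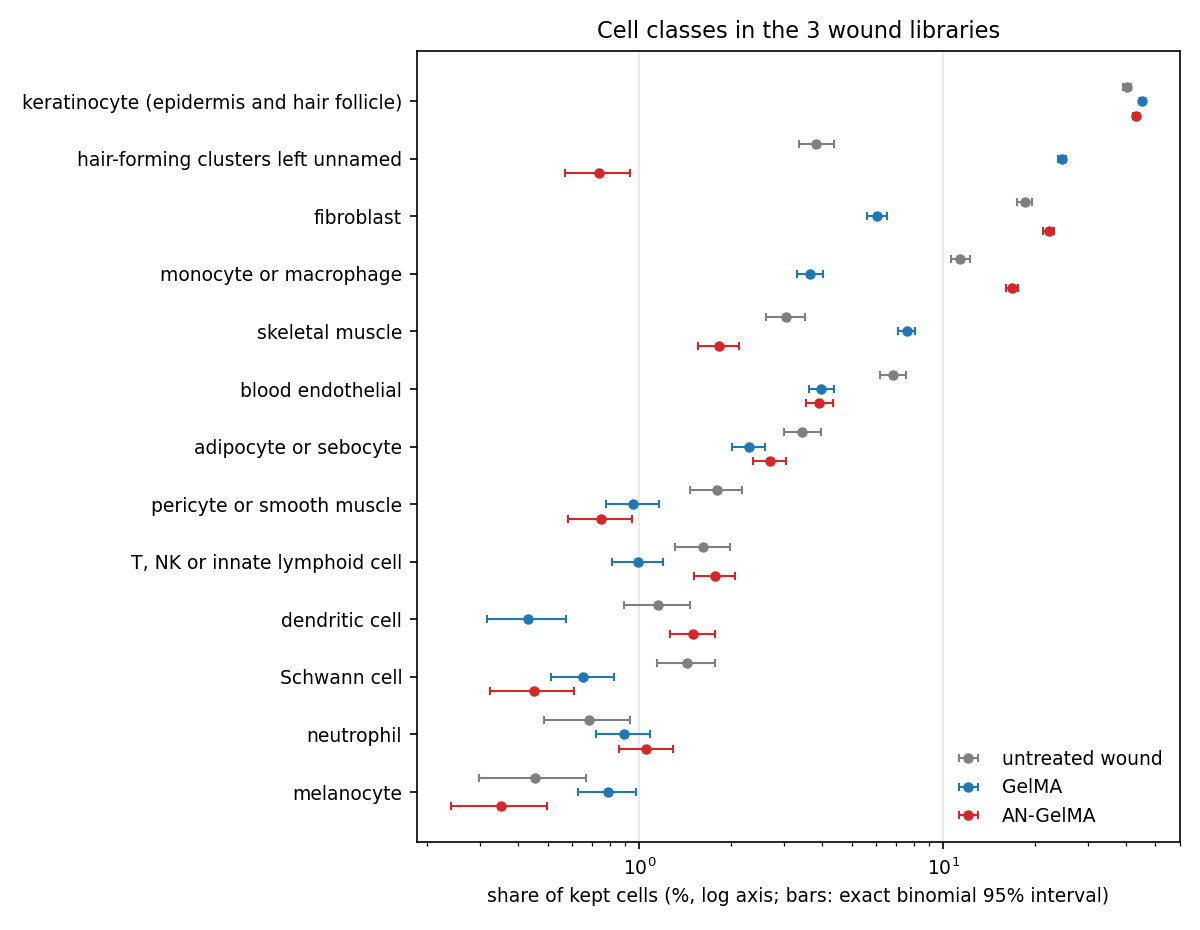
Share of each cell class among the kept cells of the untreated, GelMA and AN-GelMA libraries, on a log axis. Bars are exact binomial 95% intervals and cover counting error only. The 5 hair-forming clusters without a class are drawn on a line of their own.

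Each macrophage cluster held cells of all 3 libraries, but in a different mix. A cluster led by Cd163, Mrc1, F13a1 and Cd209f, genes of macrophages that reside in the dermis, held 212 of 390 macrophages in GelMA, 447 of 1535 in AN-GelMA and 174 of 652 in the untreated library. A cluster led by Mmp12, Rgs1 and Spp1, genes of macrophages in injured tissue, held 76 in GelMA, 724 in AN-GelMA and 356 in the untreated library. In both clusters the untreated and AN-GelMA shares were nearer each other than either was to GelMA. The macrophage values below are over both clusters and 4 smaller ones, so they carry this difference in mix, most in the comparisons with GelMA.

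With apoptotic neutrophils in the gel, macrophages of the library carried more Vegfa and Il1b RNA than with the gel alone. Vegfa, the main growth factor for blood vessels, was at 463 (430.0 to 498) CPM against 217 (171 to 272), and Il1b, an early inflammatory cytokine, at 684 (644 to 726) against 286 (232 to 347). Arg1, an enzyme of wound macrophages, was at 437 (405 to 471) against 214 (168 to 268), while Tnf was lower at 38.3 (29.3 to 49.2) against 74.2 (48.5 to 109). The mannose receptor gene Mrc1 stood at 1573 against 2353, and Mertk, a receptor for dying cells, at 227 against 251, neither past 1.5 times. Nos2 was at 48.4 (38.2 to 60.4) against 2.86 (0.0723 to 15.9) from 1 UMI, a log2 ratio of 4.08 (1.56 to 9.40). Fibroblast Nos2 differed in the same direction, at 398 CPM in AN-GelMA and 2.92 in GelMA. How much of the macrophage Nos2 came from other cells was therefore not settled. Il10 was at 32.0 against 62.8.

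Inflammatory genes were higher as a group in AN-GelMA macrophages, and genes of resident, antigen-presenting macrophages lower. The inflammatory cytokine and NF-kB list had a median log2 ratio of 0.88 [0.61 to 1.25], at percentile 100 among 10000 random lists of like size and expression, with 12 of 21 measured members higher by 1.5 times or more and 1 lower. Its neutrophil attractants Cxcl1 and Cxcl3 were at 44.6 against 8.57 and 44.0 against 8.57 CPM, each from 3 UMIs in GelMA (log2 ratios 2.38 [0.77 to 4.69] and 2.36 [0.75 to 4.67]). Cxcl1 stood higher in other classes of AN-GelMA, at 170 CPM in fibroblasts and 93.7 in neutrophils. Fixed neutrophil markers in the same macrophages had a median of 0.74 [0.23 to 0.97] at percentile 99.48, and Il1b stood at 10209 CPM in AN-GelMA neutrophils. The angiogenic list had a median of 0.30 [0.15 to 0.64] at percentile 99.64, with 9 of 19 members higher and 2 lower. Spp1 (530.0 against 99.9 CPM) and Thbs1 (1081 against 339.8) led it, whereas Cxcl12 and Mmp9 were lower at -2.09 and -1.57. Alternative activation genes were lower, with a median of -0.48 [-0.60 to -0.15] at percentile 0.04, as were MHC class II genes (-0.72 [-0.83 to -0.43], 0.02) and mature macrophage genes (-0.30 [-0.42 to -0.10], 0.230). Cd163 was at 461 against 1325 CPM, Cd74 at 725 against 1194 and Selenop at 183 against 399.8.

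Lipid handling, glycolysis and stress genes were also higher in AN-GelMA macrophages than in GelMA macrophages. The lipid-associated list, which marks macrophages filled with ingested lipid, had a median of 0.70 [0.44 to 0.79] at percentile 100, with Gpnmb at 2219 against 557 CPM and Plin2 at 874 against 443. Glycolysis and hypoxia genes had 0.60 [0.43 to 0.84] at percentile 100, with Pkm at 323 against 126 CPM, and immediate early and heat shock genes 1.01 [0.67 to 1.13] at percentile 100, led by Jun (1.51), Fosb (1.17) and Fos (1.14). Efferocytosis, the uptake of dying cells, gave 0.015 [-0.13 to 0.19] at percentile 58.4, with 6 of 28 members higher, Anxa1 (1.44) and Cd36 (1.21) among them, and 3 lower. Monocyte, interferon and cell cycle lists stayed inside the random range, with medians of 0.14 [-0.35 to 0.73], -0.22 [-0.30 to 0.095] and -0.26 [-0.45 to 0.21]. For the monocyte list this depended on processing. It stood above the range with thinned cells (0.67), members of at least 100 UMIs (0.70) and leak-filtered members (0.70), each over 5 members.

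The highest named genes in AN-GelMA macrophages were Mmp13 (2.48), Spp1 (2.41), Tppp3 (2.32), Sel1l3 (2.30), Pdpn (2.12), Dpep3 (2.00), Gpnmb (1.99), Emp1 (1.88), Lhfpl2 (1.83) and Rhob (1.81), as log2 ratios to GelMA. The lowest were the C-type lectin genes Cd209b (-3.16), Cd209g (-2.93), Cd209c (-2.24) and Cd209f (-2.17), then Fcrls (-1.68), Cd163 (-1.52), Plekhg5 (-1.39), Kmt2d (-1.25) and C4b (-1.18). Mmp13 rests on 6 UMIs in GelMA and stood at -0.45 when doublets were kept.

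The inflammatory median was 0.82 in the Cd163 and Mrc1 cluster and 0.88 in the Mmp12 and Spp1 cluster, while the angiogenic median was -0.084 and 0.052 and the lipid-associated median 0.12 and 0.0042, all 4 inside the random range. Vegfa stood at -1.29 in the first cluster, and Tnf, Cxcl1, Cd36, Mmp13 and Mmp9 at 1.29, -2.88, -0.11, -1.29 and 0.71 there. Single genes rest on few counts in this cluster. GelMA macrophages of all clusters together held 3 UMIs of Cxcl1 and 17 of Mmp9. Arg1 stood at -0.17 and Cd74 at 1.26 in the second. The medians in the first and the second were -0.88 and 0.91 for MHC class II, 0.0084 and 0.032 for mature macrophage, 0.62 and 0.46 for interferon, 0.71 and -0.0011 for glycolysis, and 1.44 and 0.10 for immediate early genes. They were -0.28 and -0.18 for alternative activation, the latter inside the random range, and 1.10 and 0.24 for cell cycle, the former above it and opposite in sign to the median over all clusters. Over all clusters the cell cycle median lay below the random range with doublets kept (-0.66) and with a class per cell (-0.62). This list was therefore called both ways. With cells thinned to 1 depth, the inflammatory median was 0.42, Tnf 0.15 and the alternative activation median -0.26, the last inside the random range. The mature macrophage call was kept in 10 of 12 alternative processings. With members passing the leak filter alone, 6 inflammatory genes remained, with a median of 0.14 inside the random range.

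**Figure D2:**
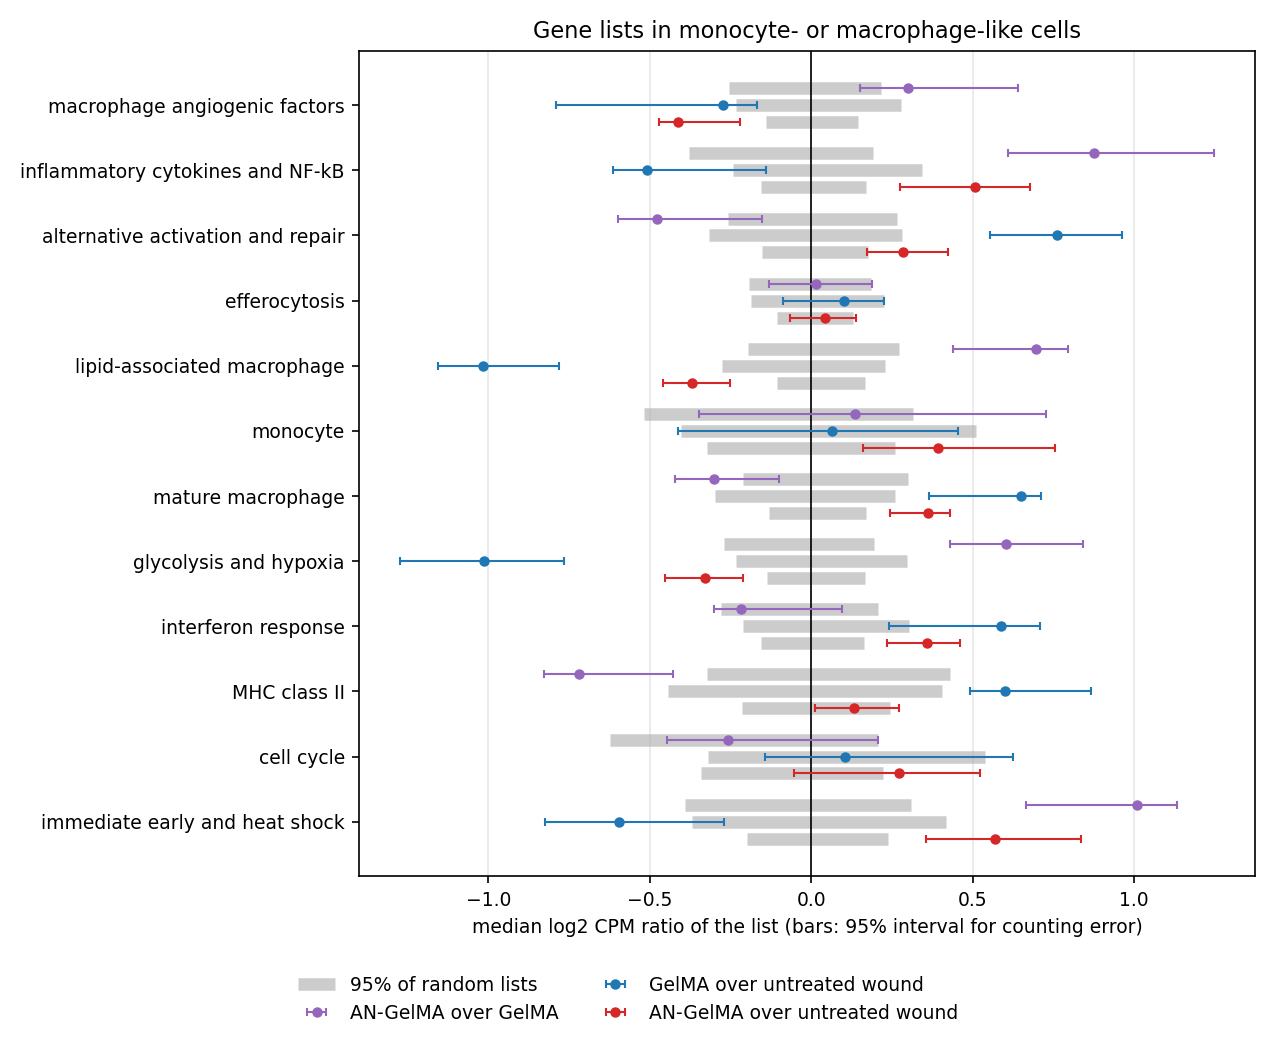
Median log2 CPM ratio of the 12 gene lists in macrophages for the 3 comparisons. Bars are 95% intervals for counting error, and grey bands hold 95% of random lists matched on size and expression.

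Against the untreated wound, the gel alone went with macrophages rich in Cd163, Cd209 genes and MHC class II, and poor in Gpnmb, Mmp12 and hypoxia genes. The gel is a cross-linked gelatin sheet, and this comparison asks what it does without cells in it. Vegfa was at 217 CPM against 634 (579 to 694) and Arg1 at 214 against 579 (525 to 636). Mrc1 was at 2353 (2195 to 2519) against 1335 (1254 to 1421), Cd163 at 1325 against 282, and the elastase gene Mmp12 at 817 against 3597. Il1b stood at 286 against 375 (333 to 422) and Mertk at 251 against 317, neither past 1.5 times. Tnf (1.05) and Il10 (0.70) were higher and Nos2 was lower at -4.36 (-9.69 to -1.80). Nos2 was lower in GelMA fibroblasts too, at 2.92 against 678 CPM.

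Glycolysis and hypoxia genes, which respond to low oxygen, had a median of -1.01 [-1.27 to -0.77] at percentile 0 in GelMA over untreated, with 14 of 17 lower; the glucose transporter gene Slc2a1 was at 97.1 against 382 CPM. Lipid-associated genes had -1.02 [-1.16 to -0.78] at 0, with Gpnmb at 557 against 3949. Inflammatory genes had -0.51 [-0.62 to -0.14] at 0, angiogenic genes -0.27 [-0.79 to -0.17] at 1.31, and immediate early genes -0.60 [-0.83 to -0.27] at 0.25, among them Il1a (-2.60), Tnfaip2 (-1.37) and Atf3 (-1.35). Higher as lists were alternative activation (0.76 [0.55 to 0.96], 100), mature macrophage (0.65 [0.37 to 0.71], 100), interferon response (0.59 [0.24 to 0.71], 99.99) and MHC class II genes (0.60 [0.49 to 0.87], 99.83), with Ms4a7 at 1048 against 564 CPM and Xaf1 at 368 against 172. Efferocytosis (0.10 [-0.087 to 0.23]), monocyte (0.064 [-0.41 to 0.45]) and cell cycle genes (0.10 [-0.14 to 0.62]) stayed inside the random range. Cell cycle genes stood above it with doublets kept (0.63) and with a class per cell (0.62). Of the efferocytosis members 5 were higher and 7 lower, where Mfge8, a bridge between dying cells and phagocytes, was lower at -1.74.

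The highest named genes in GelMA over untreated macrophages were Cd209g (2.89), Cd209c (2.77), Cd209b (2.50), Cd163 (2.23), Cd209f (2.03), Plekhg5 (1.69), C4b (1.66), Clec10a (1.43) and Fchsd2 (1.31). The lowest were Hilpda (-2.86), Gpnmb (-2.83), Cdk18 (-2.65), Spp1 (-2.49), Igf2bp2 (-2.41), Mmp12 (-2.14), Wfs1 (-2.10), Eno2 (-2.06), Il1rn (-2.00) and Slc2a1 (-1.98). In the Cd163 and Mrc1 cluster alone, Vegfa stood at 0.57, Tnf at -0.014, Il10 at -0.17, Mfge8 at 0.40, and the interferon, inflammatory and angiogenic medians at -0.44, -0.098 and -0.11. In the Mmp12 and Spp1 cluster alone, the MHC class II median was -0.91, the inflammatory median -0.0029 and the immediate early median 0.38; with thinned cells the interferon and angiogenic medians were 0.13 and -0.29, inside the random range. With at least 1000 UMIs per cell the inflammatory median was -0.30, also inside, and the immediate early call was kept in 9 of 12 alternative processings. The MHC class II and mature macrophage medians were 0.17 and 0.014 in the Cd163 and Mrc1 cluster, and the lipid-associated and interferon medians -0.23 and 0.092 in the Mmp12 and Spp1 cluster, all inside.

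The whole treatment, compared with the untreated wound, showed more inflammatory and immediate early RNA in macrophages and less of the angiogenic and lipid-associated genes. Il1b was at 684 CPM against 375, and Fos, a gene induced within minutes of stimulation or handling, at 911 against 446. Vegfa stood at 463 against 634 and Arg1 at 437 against 579, within 1.5 times, as did Tnf (0.093), Mrc1 (0.24), Mertk (-0.48), Nos2 (-0.28) and Il10 (-0.27). Mmp12 was lower at 1586 against 3597 CPM, as were Gpnmb (-0.83) and Mfge8 (87.3 against 229).

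The inflammatory list had a median of 0.51 [0.28 to 0.68] at percentile 100, with 10 of 21 members higher and 1 lower, and immediate early genes 0.57 [0.36 to 0.83] at 100. Neutrophil markers in these macrophages had a larger median of 0.78 [0.44 to 1.17] at 99.99; with the level reached by markers of other classes taken off, the inflammatory median was 0.56 [0.27 to 0.67]. The angiogenic list had -0.41 [-0.47 to -0.22] at 0, lipid-associated genes -0.37 [-0.46 to -0.25] at 0 and glycolysis -0.33 [-0.45 to -0.21] at 0. Interferon (0.36 [0.23 to 0.46]), mature macrophage (0.36 [0.24 to 0.43]), alternative activation (0.28 [0.17 to 0.42]), monocyte (0.39 [0.16 to 0.75]) and cell cycle genes (0.27 [-0.053 to 0.52]) lay above the random range, with Ifit3 (0.82), Cd163 (0.71) and Vcan (0.70) higher. The cell cycle call was kept in 2 of 10 alternative processings. Inside the random range were alternative activation (0.18) and mature macrophage genes (0.26) with thinned cells, and monocyte (0.11) and glycolysis genes (-0.16) at 1000 UMIs per cell. In the Cd163 and Mrc1 cluster alone alternative activation (0.19), mature macrophage (-0.021), interferon (0.20), monocyte (0.47) and glycolysis genes (-0.12) lay inside it, as did monocyte genes in the Mmp12 and Spp1 cluster (0.26). Over all clusters MHC class II (0.13 [0.013 to 0.27]) and efferocytosis genes (0.043 [-0.065 to 0.14]) lay inside as well. With leak-filtered members the inflammatory median was 0.021, inside the random range, and the immediate early median -0.37, below it; with members of at least 100 UMIs the angiogenic median was -0.11, inside it. The highest named genes were Ly6a (1.21), Cfb (1.06), Fos (1.03), Tppp3 (1.03), Eef1a1 (1.00), Tapbp (0.98), Phf11b (0.97), Tet3 (0.96), Cep295nl (0.95) and Ms4a6b (0.94); the lowest were Mfge8 (-1.39), Wfs1 (-1.31), Mmp12 (-1.18), Rgs11 (-1.17), Cdk18 (-1.12), Ankrd37 (-1.03), Plk2 (-0.95), Rhoc (-0.91), Igf2bp2 (-0.85) and Zranb3 (-0.85). Wfs1 stood at 0.28 in the Cd163 and Mrc1 cluster alone.

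**Figure D3:**
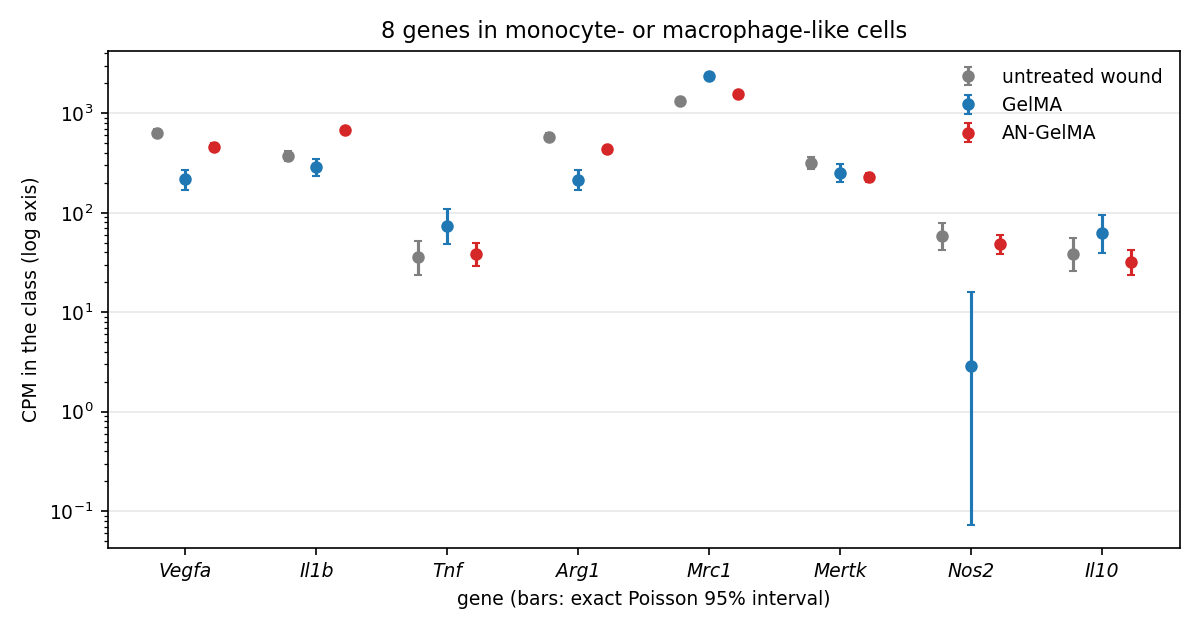
CPM of 8 genes in macrophages of the untreated, GelMA and AN-GelMA libraries, on a log axis. Bars are exact Poisson 95% intervals.

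RNA of other cell types was present in the macrophage class and differed between libraries. The keratin gene Krt14 was at 150.3, 294 and 148 CPM in macrophages of the untreated, GelMA and AN-GelMA libraries, Krt10 at 10.6, 28.6 and 8.79, and the hair gene Tchh at 86.5, 477 and 15.1, with 7122, 15732 and 236 in the hair-forming clusters. The filter against leaked RNA did not read clusters without a class, so Tchh is also named in other classes below. Fibroblast Col1a1 was at 271, 451 and 209, Col3a1 at 206, 228 and 156 and Dcn at 5.32, 11.4 and 6.28; Pecam1 was at 23.9, 40.0 and 18.2, muscle Acta1 at 1.33, 31.4 and 2.51 and Cd3e at 0, 0 and 3.77. Neutrophil S100a8 was at 7.98, 17.1 and 37.7, S100a9 at 20.0, 40.0 and 31.4 and Retnlg at 1.33, 5.71 and 0.628. No UMI of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y was seen in any library, so they say nothing about the neutrophil donors.

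Neutrophils could be compared only between AN-GelMA (96 cells) and GelMA (95), since the untreated library held 39. The AN-GelMA gel was itself loaded with neutrophils, so host and loaded cells cannot be told apart in that library. Csf3r, the receptor for granulocyte colony-stimulating factor on mature neutrophils, was at 3434 CPM against 605, and Cxcr2, a homing receptor, at 354 against 89.9. The granule genes Ltf and Ngp of less mature cells had 0 UMIs in AN-GelMA and 33 and 20 in GelMA, at least 8.64-fold and 5.23-fold lower. The chemokine genes Ccl3 and Ccl4 were lower at 1197 against 4060.5 and 656 against 3415 CPM. All 5 measured interferon genes were higher, among them Isg15 (2.60) and Oasl2 (2.50), with a median of 1.55 [1.01 to 2.52] at percentile 99.75; with thinned cells the median was 1.09, inside the random range.

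The neutrophil activation list had a median of -0.27 [-0.54 to -0.050] at percentile 1.61, a call kept in 7 of 11 alternative processings. Maturity (0.0012 [-0.46 to 0.61]), inflammatory (-0.13 [-0.40 to 0.022]), glycolysis (-0.19 [-0.59 to -0.023]) and immediate early genes (-0.0032 [-0.41 to 0.43]) stayed inside the random range. The highest named genes were Csf3r (2.51), Slfn4 (2.45), Csf2rb (2.26) and Cd33 (2.16); the lowest were Tchh (-4.35), Spp1 (-2.57), Ccl4 (-2.38) and Cxcl3 (-1.99). Tchh, a hair gene, stood at 16756 CPM in the unnamed clusters of GelMA against 1062 in its neutrophils.

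Fibroblasts of the GelMA library nearly lacked Nos2 and were low in genes of glycolysis and hypoxia. Nos2, which makes nitric oxide, was at 2.92 CPM from 2 UMIs in GelMA, 398 in AN-GelMA and 678 in the untreated library. In the same order, the matrix gene Fn1 was at 562, 1517 and 1190.0 CPM and Tnc at 217, 565 and 403. A fibroblast cluster with Nos2 among its leading genes held 23 of 649 fibroblasts in GelMA, 411 of 2023 in AN-GelMA and 205 of 1061 in the untreated library. Elastin (Eln) went the other way, at 553, 298 and 241 CPM, and the lymphocyte chemokine gene Ccl19 at 169, 38.3 and 47.0.

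In AN-GelMA over GelMA fibroblasts, glycolysis and hypoxia had a median of 1.31 [1.11 to 1.59] (17 of 19 higher), fibrillar matrix 0.32 [0.20 to 0.35], contractile genes 0.42 [0.30 to 0.54], proteases 0.30 [0.042 to 0.37], cell cycle 0.49 [0.24 to 0.63] and interferon 0.45 [0.25 to 0.69], all above the random range. Chemokines (0.15 [-0.026 to 0.68]) and immediate early genes (-0.018 [-0.26 to 0.25]) lay inside it, although chemokines stood above it in 7 of 12 alternative processings. GelMA over untreated gave -1.85 [-1.97 to -1.53] for glycolysis (18 of 18 lower), -0.25 [-0.34 to -0.18] for matrix, -0.42 [-0.50 to -0.23] for contractile genes and -0.62 [-0.90 to -0.40] for cell cycle, all below the random range, and 0.26 [-0.063 to 0.45] for chemokines and 0.63 [0.25 to 0.90] for immediate early genes, above it. Proteases (-0.085 [-0.19 to 0.097]) and interferon (-0.039 [-0.36 to 0.045]) lay inside. AN-GelMA over untreated gave 0.50 [0.33 to 0.67] for chemokines, with Ptx3, Cxcl1 and Il6 at 1.16, 1.13 and 0.93, and 0.51 [0.34 to 0.71] for immediate early, 0.17 [0.14 to 0.42] for interferon and 0.20 [0.047 to 0.28] for proteases, all above the random range. Glycolysis (-0.37 [-0.50 to -0.19]) and cell cycle (-0.30 [-0.38 to -0.067]) lay below it, and matrix (0.0014 [-0.043 to 0.065]) and contractile genes (0.084 [-0.024 to 0.15]) inside.

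Several of these fibroblast calls depend on processing. For AN-GelMA over GelMA, the cell cycle call was kept in 10 of 12 alternative processings, with 0.044 with a class per cell and 0.24 with thinned cells. The protease call was kept in 10 of 12 and ended without the Nos2 cluster (0.12), the contractile call was kept in 9 of 12 and the matrix call in 11 of 12, while glycolysis and interferon were kept in all 12. For GelMA over untreated, the immediate early call was kept in 7 of 11, with 0.28 for the mean of per-cell CPM, the chemokine call in 4 of 12, with a call of the other sign for thinned cells and the mean of per-cell CPM (-0.31), the contractile call in 7 of 12 and the matrix call in 11 of 12; glycolysis and cell cycle were kept in all 12. For AN-GelMA over untreated, the protease and cell cycle calls were each kept in 11 of 12, and the others in every one.

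The highest named fibroblast genes were Nos2 (7.09 [5.24 to 10.14]), Sh2d6 (3.58 [2.00 to 5.88]), Serpinb2 (3.33) and Ptgis (2.80) in AN-GelMA over GelMA, Adamts18 (5.73), Tchh (3.29), Ccl19 (1.85) and Dpep1 (1.8) in GelMA over untreated, and Ptx3 (1.16), Cxcl1 (1.13), Prg4 (1.12) and Adamts15 (1.11) in AN-GelMA over untreated. The lowest were Adamts18 (-5.74), Tchh (-5.54), Ccl19 (-2.14) and Abca8a (-2.07), then Nos2 (-7.86 [-10.91 to -6.0]), Ptgs2 (-2.68) and Serpinb2 (-2.64), and Ero1a (-0.93), Pik3c3 (-0.83), Nos2 (-0.77) and Cbx6 (-0.75). Without the Nos2 cluster, Nos2 and Cxcl1 in AN-GelMA over untreated stood at 1.01 and -0.055, the glycolysis median there at 0.050, and Ptgs2 in GelMA over untreated at 0.098. The contractile median of AN-GelMA over GelMA stood at -0.043 in cells of at least 1000 UMIs and -0.25 after the leak filter, and the chemokine median of GelMA over untreated at -0.31 with thinned cells.

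Blood endothelial cells of AN-GelMA held more RNA of sprouting genes than those of GelMA, at a level near the untreated wound. Esm1 and Angpt2, genes of tip cells that lead new vessels, were at 96.7 CPM against 5.03 (from 2 UMIs; log2 ratio 4.26, 2.31 to 7.36) and 246 against 55.4. The basement membrane gene Nid2 was at 358 against 80.6, while Aplnr was lower at 13.1 against 50.3. The sprouting list had a median of 0.43 [0.28 to 0.64] at percentile 99.91 for AN-GelMA over GelMA, -0.48 [-0.64 to -0.33] at 0.01 for GelMA over untreated, and -0.045 [-0.15 to 0.070] at 30.4 for AN-GelMA over untreated. The first pair of calls was kept in all 12 alternative processings. Against the untreated library GelMA was lower in Igfbp3 (138 against 608 CPM) and higher in the flow-responsive gene Klf2 (725 against 226).

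Endothelial cell cycle genes had medians of 0.38 [0.054 to 0.71], -0.79 [-0.96 to -0.39] and -0.079 [-0.43 to 0.046] for AN-GelMA over GelMA, GelMA over untreated and AN-GelMA over untreated; the first pair lay outside the random range, and with doublets kept the first was 0.070, inside it, a call kept in 7 of 11 alternative processings. Adhesion genes, which let leukocytes attach, gave 0.030 [-0.34 to 0.22], -0.063 [-0.27 to 0.22] and -0.25 [-0.43 to 0.060], all inside. Interferon genes gave -0.24 [-0.53 to -0.068], -0.063 [-0.15 to 0.30] and -0.35 [-0.53 to -0.063], and immediate early genes 0.11 [-0.36 to 0.35], 0.52 [0.13 to 0.91] and 0.46 [0.094 to 0.84], with the last of each outside; those calls were kept in 10 of 12 and 8 of 10 alternative processings. Other named genes were Col13a1 (2.50), Ccn2 (1.90) and Igfbp3 (1.8) above and Tchh (-5.35), Ablim3 (-2.33), Ccdc85a (-2.01) and Cdc42ep1 (-1.73) below GelMA in AN-GelMA, Tchh (4.69), Ccdc85a (1.95) and Ablim3 (1.74) above and Nid2 (-1.95), Pkm (-1.62) and Prnd (-1.47) below untreated in GelMA, and Col13a1 (1.52), Adamts1 (1.12), Ccn1 (0.91) and Nup85 (0.87) above and Myo10 (-1.14), Atp13a3 (-1.07), Cxcl12 (-1.05) and Chd6 (-1.03) below untreated in AN-GelMA.

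Keratinocytes of GelMA carried more hair shaft RNA than those of AN-GelMA, with untreated keratinocytes between them for some genes and nearly without others. The keratin-associated gene Krtap28-13 was at 202 CPM in GelMA, 67.2 untreated and 1 UMI in AN-GelMA, while Krtap19-5, Krtap2-4, Krtap6-2 and Krtap15 had 1, 1, 1 and 2 UMIs untreated. Krt83, Krt33a and Krt86, keratins of the hair cortex, were at 495, 474 and 392 CPM in GelMA and at 1 UMI each in AN-GelMA (log2 ratios -11.76 [-17.07 to -9.28], -11.70 [-17.00 to -9.22] and -11.43 [-16.73 to -8.95]); they are leading genes of the hair shaft cluster, with 284 cells in GelMA. The outer root sheath cluster held 1574 of 4836 keratinocytes in GelMA, and a basal cluster (Col17a1, Itgb4, Krt15) was the largest in the untreated and AN-GelMA libraries with 849 and 1459. The injury keratin Krt6a was at 857 CPM in GelMA, 350.4 in AN-GelMA and 366 untreated, and the growth factor gene Hbegf at 66.3, 24.4 and 28.5. Krt6a also met the marker limit in the outer root sheath cluster, and its value was not separated from the mix of clusters. Fst, an activin inhibitor, was at 68.5 in GelMA against 261 untreated, and the collagenase gene Mmp13 at 25.1 against 93.3.

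The keratinocyte wound activation list stayed inside the random range in all 3 comparisons, with -0.097 [-0.19 to -0.010] for AN-GelMA over GelMA, 0.16 [0.070 to 0.25] for GelMA over untreated and -0.017 [-0.088 to 0.085] for AN-GelMA over untreated. This depended on processing: GelMA over untreated stood above the random range at 1000 UMIs per cell (0.69) and Leiden resolution 2 (0.71), and at -0.19 with a class per cell, inside it. AN-GelMA over untreated stood above it at resolution 2 (0.26), and AN-GelMA over GelMA below it there (-0.30). Differentiation gave -0.024 [-0.12 to 0.051], 0.37 [0.33 to 0.42] and 0.043 [0.012 to 0.16], with the second above the random range. The first was called below it in some processings and above it in others (-0.30 at resolution 2, 0.47 with thinned cells); the second stood at -0.20 with thinned cells and was kept in 10 of 12 alternative processings. Cell cycle gave -0.030 [-0.18 to 0.027], -0.25 [-0.33 to -0.095] and -0.28 [-0.36 to -0.16], with the last pair below; the second stood at 0.32 with a class per cell, a call of the other sign, and was kept in 7 of 11. Interferon gave 0.33 [0.22 to 0.47], -0.019 [-0.17 to 0.11] and 0.35 [0.15 to 0.49], and immediate early genes 0.22 [0.13 to 0.32], -0.19 [-0.26 to 0.11] and 0.26 [0.036 to 0.37], with the first and last of each above; without the hair shaft and outer sheath clusters the first interferon median was 0.15 and the first immediate early median -0.076, inside the random range. The last immediate early call was kept in 10 of 12. Named genes past those above were Sectm1b (1.99), Aldh3a1 (1.89), Vwa2 (1.89) and Neurl1b (1.64) higher and Krtap28-13 (-10.47 [-15.77 to -7.99]) lower in AN-GelMA over GelMA, Krtap19-5 (9.77 [7.29 to 15.07]), Krtap2-4 (9.37 [6.89 to 14.67]), Krtap6-2 (8.26 [5.78 to 13.57]) and Krtap15 (7.78 [5.93 to 10.83]) higher and Vwa2 (-1.95) and Skint7 (-1.56) lower in GelMA over untreated, and Prr9 (1.99), Il36a (1.24), Fetub (1.16) and Atp12a (1.10) higher in AN-GelMA over untreated. The lowest there were Krtap28-13 (-8.88 [-14.19 to -6.39]), Vsig8 (-7.41 [-12.73 to -4.90]), Krtap10-10 (-6.44) and Krtap5-2 (-6.41 [-9.47 to -4.52]), with 1, 1, 6 and 2 UMIs in AN-GelMA; Krtap5-2 and Prr9 stood at 0.30 and -1.87 with doublets kept.

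**Figure D4:**
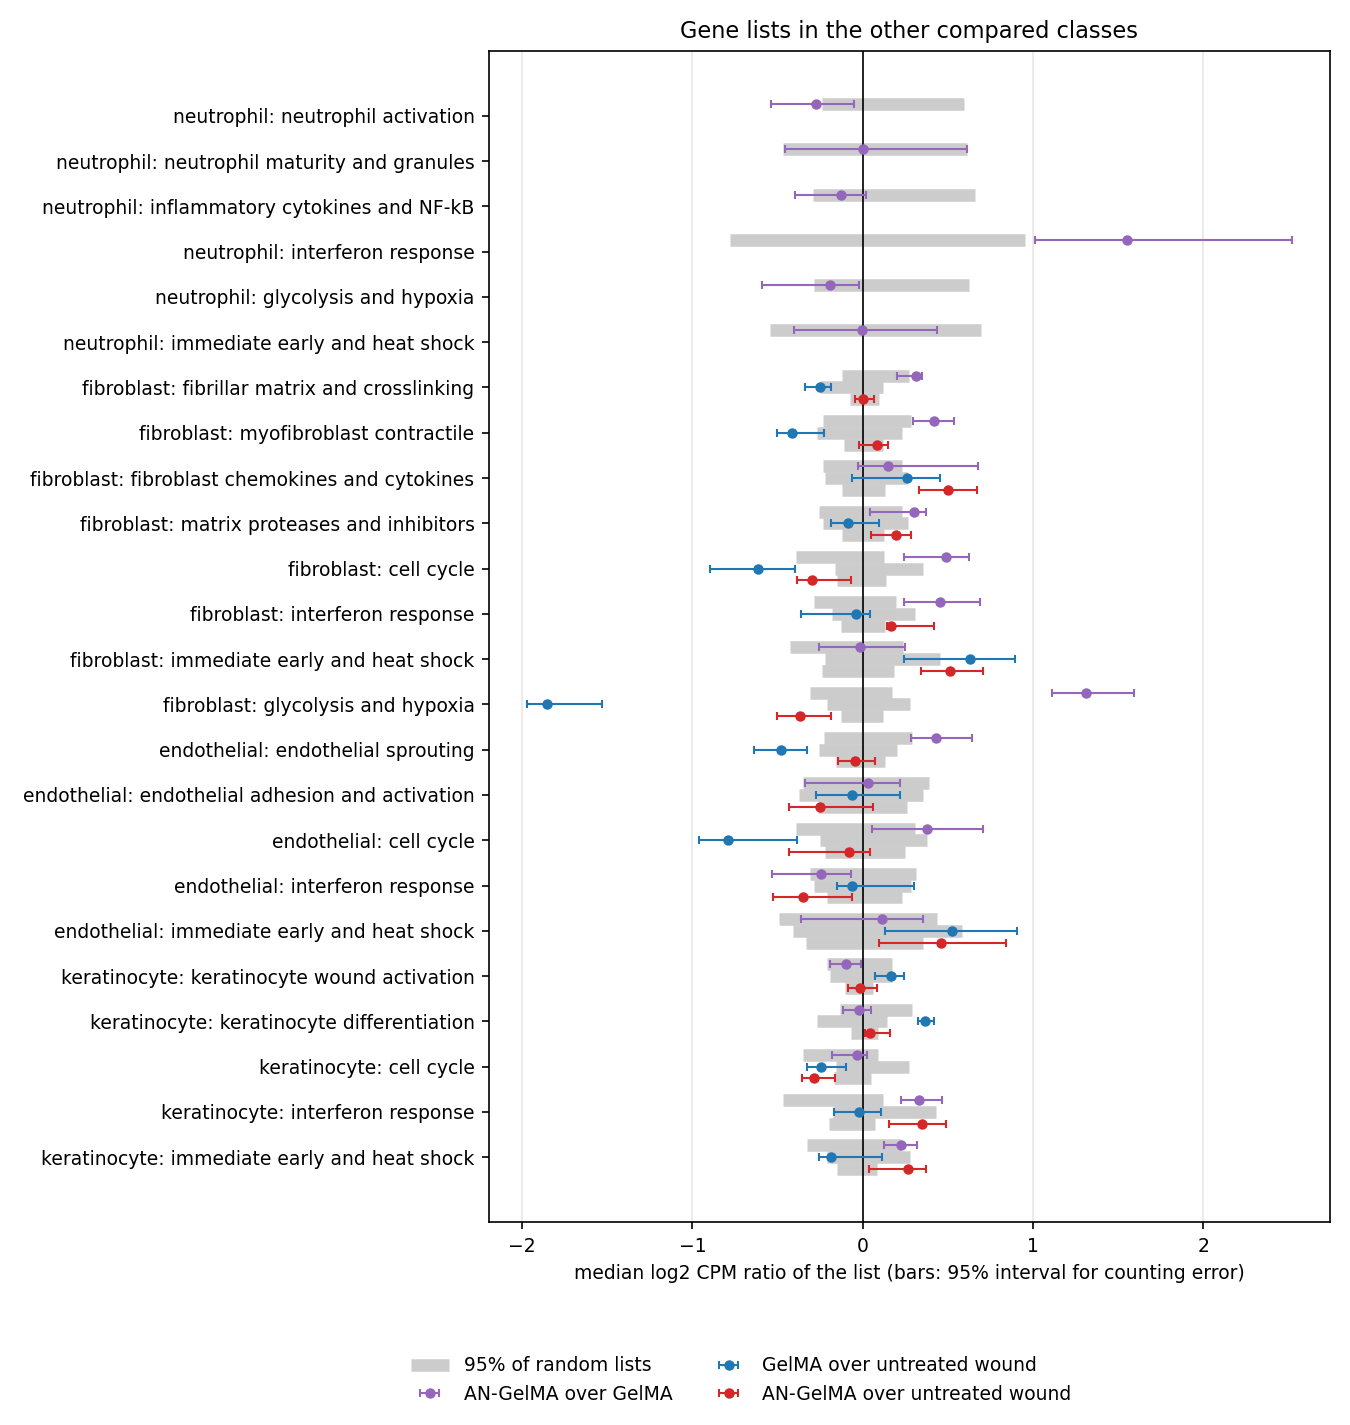
Median log2 CPM ratio of the gene lists in neutrophils, fibroblasts, blood endothelial cells and keratinocytes, with 95% intervals for counting error. Grey bands hold 95% of random lists. Neutrophils were compared only between AN-GelMA and GelMA.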

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

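The tests on dilution, surrounding skin, hair stage, marker-level RNA from other cells and neutrophil transcripts were chosen after the results were seen, as was the test of single macrophage clusters, whose bounds for both clusters together, unlike that for the second alone, were written before its values were seen; the tests by the leak filter and by thinning were planned. The hair-forming clusters without a class, which the gene comparisons leave out, held 24.6% of the GelMA cells. They held 3.83% of the untreated and 0.737% of the AN-GelMA cells, and this large part of 1 library outside the comparisons is why it is listed here.

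The first pattern is the makeup of the GelMA library, with few macrophages and fibroblasts and many hair-forming cells. Dilution by hair-forming, other unnamed, muscle and pigment cells as the whole cause is argued against: without them macrophages were 5.84% [5.29 to 6.43] in GelMA and 13.1% [12.2 to 14.1] untreated. The outer root sheath type cluster, with 14.7% of GelMA and 2.62% of untreated cells, stayed in the denominator. Dilution by all follicle cells together was therefore not tested. A larger piece of surrounding skin with follicles in the same state is argued against as well. Hair-forming cells per upper-follicle cell were 9.72 in GelMA and 0.780 [0.652 to 0.933] untreated. In AN-GelMA they were 0.122 [0.0931 to 0.157], so the ratio also differed between the libraries other than GelMA. The hair growth stage of the animal or the place of the piece taken, and an effect of the gel, cannot be told apart at 27.3% hair-forming cells, since GelMA has 1 library.

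The second pattern is the higher inflammatory and angiogenic lists in AN-GelMA over GelMA macrophages. For the angiogenic list (0.30 [0.15 to 0.64]) a different mix of clusters is a candidate explanation, since the median was -0.084 [-0.46 to 0.28] in the Cd163 and Mrc1 cluster and 0.052 [-0.16 to 0.36] in the Mmp12 and Spp1 cluster, both inside the random range; Mmp12 and Spp1, which lead the second cluster, are themselves in the list. For the inflammatory list (0.88 [0.61 to 1.25]) the medians were 0.82 [0.36 to 1.23] and 0.88 [0.39 to 1.04], which argues against the mix as the whole cause, since the lower bound in the second clears its random range, which ends at 0.32; in the first it lies below the end of 0.55 over 10 members, so a part played there stays open. Tests of RNA from other cell classes point apart. With the 6 of 21 members that pass the leak filter the median was 0.14 [-0.049 to 0.51], inside the random range. The call ended because members with more than 2 times the CPM in another class left the list. Taking off the level that other cells' markers reach in macrophages gave 1.12 [0.83 to 1.36], still above the random range. That step also raised the median over all measured genes from -0.095 to 0.089, so the rise from 0.88 is in part built in. With cells thinned to 1 depth the median was 0.42 [0.13 to 0.86], above the random range with a lower bound inside it, so unequal depth stays open, and an effect of the apoptotic neutrophils stays untested.

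The third pattern is a higher median of neutrophil markers in AN-GelMA macrophages, where RNA of the loaded neutrophils may have been taken up or released nearby. Of 13 fixed neutrophil markers, 8 were measured in macrophages. Their median log2 ratio over GelMA was 0.74 [0.23 to 0.97], against an upper end of the random range of 0.53. By 1.5 times or more, 5 were higher, among them S100a8 (1.14) and Csf3r (0.72), and 1, Mmp9 (-1.57), was lower. S100a9 (-0.35) and Acod1 (0.40) stayed within 1.5 times. Of the higher markers, S100a8, Hdc, Trem1 and Mmp8 rest on 6, 3, 1 and 0 UMIs in GelMA, the last giving a bound. Over untreated AN-GelMA gave 0.78 [0.44 to 1.17], wholly above the upper end of 0.37, and GelMA 0.37 [-0.013 to 0.84], inside the random range. Mmp9 and Acod1 are also in the angiogenic and inflammatory lists, and S100a8 reached 37.7 CPM in AN-GelMA macrophages and 3746 in its neutrophils. Host neutrophils, loaded neutrophils and expression by monocytes cannot be told apart, since the interval over GelMA spans the end of the random range and the donors carry no mark in these counts.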

How the results depend on the processing

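The alternatives on single macrophage clusters, hair-forming clusters, the Nos2 cluster of fibroblasts, small clusters and the cells left out of the denominator were chosen after the data were seen; the others were planned. Of 5122 values of named genes under all alternatives, 4280 stayed within their counting interval, 763 lay outside it and 79 were called and turned sign. Of 1242 list medians the counts were 1015, 198 and 29, and of 351 cell shares 224, 127 and 0. Of the 60 list calls, 58 were kept with no filter on cells and 59 with TMM factors. These settings could change little. The filter had removed 217 of 27170 barcodes. TMM factors shift list members and random lists of a class by the same amount, so a call could hardly change. Both settings are included in the counts out of up to 12 given for single calls. At Leiden resolution 2 and 0.5, 60 and 56 calls were kept. With doublets kept the number was 53, with the mean of per-cell CPM 52 and with a class per cell 51. Of 59 that thinned cells could give, 43 were kept, and of 58 at 1000 UMIs per cell 47, where neutrophils fell below 50 cells and gave no value. With list members of at least 100 UMIs 52 of 56 were kept, with members of at least 1 UMI 56 of 60, and after the leak filter 43 of 52. In the Cd163 and Mrc1 cluster alone 13 of 27 were kept and 1 had the other sign, and in the Mmp12 and Spp1 cluster alone 13 of 27 and 2. Without the Nos2 cluster 15 of 18 were kept, and 5 of 7 under each of the settings on hair clusters. Some lists inside the random range were called under other settings. Among them were chemokines in AN-GelMA over GelMA fibroblasts (8 of 13) and adhesion in AN-GelMA over untreated endothelial cells (6 of 12). Others were wound activation in GelMA over untreated keratinocytes (6 of 14), and monocyte (4 of 14) and cell cycle genes (3 of 11) in AN-GelMA over GelMA macrophages. Differentiation in AN-GelMA over GelMA keratinocytes was called in 7 of 14 and went both ways, 5 (-0.46 to -0.21) below the random range and 2 (0.40 to 0.47) above it. In AN-GelMA over GelMA macrophages the angiogenic call was kept in 12 of 12 planned settings (0.30 to 0.85) and the inflammatory call in 11 of 12 (0.14 to 1.14).

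Each value below is the log2 CPM ratio or list median under the alternative, with the reported value after "from", and a value without a call that crosses 0 is given as a move. The cause of these moves was not tested except where the construction of the alternative shows it. With at least 1000 UMIs per cell, called signs turned in GelMA over untreated endothelial cells for Jun -0.0038 (from 1.18), in AN-GelMA over GelMA fibroblasts for Tagln -0.092 (from 0.80) and contractile list -0.043 (from 0.42), in GelMA over untreated fibroblasts for Acta2 0.066 (from -0.78), in AN-GelMA over GelMA keratinocytes for Gbp2 -0.26 (from 0.97) and in AN-GelMA over untreated keratinocytes for Krt6b 0.14 (from -0.67), Krtap5-2 0.26 (from -6.41), Lor -0.16 (from 0.71), S100a8 0.75 (from -0.60) and S100a9 0.60 (from -0.80). Other values moved outside their interval in AN-GelMA over GelMA endothelial cells for sprouting list 0.66 (from 0.43), in AN-GelMA over untreated endothelial cells for sprouting list 0.089 (from -0.045), in AN-GelMA over untreated fibroblasts for matrix list 0.081 (from 0.0014), in AN-GelMA over untreated keratinocytes for wound activation list 0.14 (from -0.017) and in GelMA over untreated keratinocytes for wound activation list 0.69 (from 0.16). Fibroblasts were 20.4% (from 22.2%) in AN-GelMA and 3.83% (from 6.07%) in GelMA, macrophages were 10.5% (from 16.9%) in AN-GelMA, 1.25% (from 3.65%) in GelMA and 9.36% (from 11.4%) in the untreated library and neutrophils were 0.604% (from 1.06%) in AN-GelMA and 0.411% (from 0.889%) in GelMA. With doublets kept, called signs turned in AN-GelMA over untreated keratinocytes for Krtap5-2 0.30 (from -6.41), Lor -0.48 (from 0.71) and Prr9 -1.87 (from 1.99) and in AN-GelMA over GelMA macrophages for Mmp13 -0.45 (from 2.48). Moves outside the interval were seen in AN-GelMA over GelMA fibroblasts for matrix list 0.37 (from 0.32) and in GelMA over untreated keratinocytes for wound activation list 0.26 (from 0.16). Macrophages were 18.3% (from 16.9%) in AN-GelMA and 12.6% (from 11.4%) in the untreated library. At Leiden resolution 0.5, called signs turned in AN-GelMA over untreated keratinocytes for Krtap5-2 0.27 (from -6.41), Lor -0.41 (from 0.71) and Prr9 -0.15 (from 1.99). Further moves were seen in GelMA over untreated macrophages for inflammatory list -0.64 (from -0.51). Macrophages were 18.8% (from 16.9%) in AN-GelMA, 4.16% (from 3.65%) in GelMA and 12.8% (from 11.4%) in the untreated library. At resolution 2, called signs turned in AN-GelMA over untreated keratinocytes for Krtap5-2 0.25 (from -6.41), Lor -0.30 (from 0.71), S100a8 0.33 (from -0.60) and S100a9 0.26 (from -0.80). Outside their interval, with no call turned, were values in AN-GelMA over GelMA keratinocytes for wound activation list -0.30 (from -0.097), in AN-GelMA over untreated keratinocytes for wound activation list 0.26 (from -0.017) and in GelMA over untreated keratinocytes for wound activation list 0.71 (from 0.16). With a class per cell, called signs turned in AN-GelMA over GelMA endothelial cells for Dnajb1 0.87 (from -0.85), in GelMA over untreated fibroblasts for chemokine list -0.0093 (from 0.26), in AN-GelMA over untreated keratinocytes for Krtap5-2 0.90 (from -6.41), in GelMA over untreated keratinocytes for cell cycle list 0.32 (from -0.25), in AN-GelMA over GelMA macrophages for Aurkb -0.088 (from 1.22) and Cenpa -0.032 (from 0.77), in AN-GelMA over untreated macrophages for cell cycle list -0.21 (from 0.27) and in GelMA over untreated macrophages for Dnajb1 0.55 (from -0.71). Other values moved outside their interval in AN-GelMA over GelMA fibroblasts for matrix list 0.64 (from 0.32), in AN-GelMA over untreated fibroblasts for matrix list 0.094 (from 0.0014), in GelMA over untreated fibroblasts for matrix list -0.51 (from -0.25), in AN-GelMA over GelMA keratinocytes for wound activation list 0.13 (from -0.097), in GelMA over untreated keratinocytes for wound activation list -0.19 (from 0.16) and in AN-GelMA over GelMA neutrophils for activation list -0.59 (from -0.27). Fibroblasts were 24.1% (from 22.2%) in AN-GelMA, 8.22% (from 6.07%) in GelMA and 22.6% (from 18.5%) in the untreated library, macrophages were 14.8% (from 16.9%) in AN-GelMA and 9.75% (from 11.4%) in the untreated library and neutrophils were 1.39% (from 1.06%) in AN-GelMA and 1.07% (from 0.682%) in the untreated library. No filter on cells moved none of the main list medians or shares.

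With TMM factors, values moved in AN-GelMA over GelMA fibroblasts for matrix list 0.49 (from 0.32), in GelMA over untreated fibroblasts for matrix list -0.37 (from -0.25) and in GelMA over untreated macrophages for inflammatory list -0.66 (from -0.51). With the mean of per-cell CPM, called signs turned in GelMA over untreated fibroblasts for chemokine list -0.31 (from 0.26) and in GelMA over untreated keratinocytes for differentiation list -0.0027 (from 0.37). Moves outside the interval were seen in AN-GelMA over untreated fibroblasts for matrix list -0.056 (from 0.0014), in AN-GelMA over GelMA keratinocytes for wound activation list 0.051 (from -0.097), in GelMA over untreated keratinocytes for wound activation list 0.0022 (from 0.16) and in GelMA over untreated macrophages for inflammatory list -0.68 (from -0.51). With cells thinned to 500 UMIs, called signs turned in AN-GelMA over untreated fibroblasts for Egr1 -0.32 (from 0.78) and Mmp13 0.49 (from -1.16), in GelMA over untreated fibroblasts for Cnn2 0.095 (from -0.64) and chemokine list -0.31 (from 0.26), in GelMA over untreated keratinocytes for cell cycle list 0.033 (from -0.25) and differentiation list -0.20 (from 0.37), in AN-GelMA over GelMA macrophages for H2-DMb1 0.18 (from -0.92), Isg15 0.22 (from -0.86) and Tnf 0.15 (from -0.95) and in AN-GelMA over untreated macrophages for Ccl4 -1.58 (from 0.99), Ccna2 -2.00 (from 1.40), Ifitm6 -0.42 (from 0.81), Osm -0.74 (from 0.94), Retnla -3.17 (from 0.88) and Stab1 -0.021 (from 0.61). Further moves were seen in GelMA over untreated endothelial cells for sprouting list -0.32 (from -0.48), in AN-GelMA over GelMA fibroblasts for matrix list 0.38 (from 0.32), in GelMA over untreated fibroblasts for matrix list -0.35 (from -0.25), in AN-GelMA over untreated keratinocytes for wound activation list -0.15 (from -0.017), in GelMA over untreated keratinocytes for wound activation list 0.0031 (from 0.16), in AN-GelMA over GelMA macrophages for inflammatory list 0.42 (from 0.88) and in GelMA over untreated macrophages for inflammatory list -0.65 (from -0.51). With list members of at least 100 UMIs, called signs turned in AN-GelMA over untreated macrophages for cell cycle list -0.20 (from 0.27). Outside their interval, with no call turned, were values in AN-GelMA over GelMA macrophages for inflammatory list 0.56 (from 0.88), in AN-GelMA over untreated macrophages for inflammatory list 0.25 (from 0.51) and angiogenic list -0.11 (from -0.41) and in GelMA over untreated macrophages for angiogenic list -0.80 (from -0.27). With members of at least 1 UMI, called signs turned in AN-GelMA over untreated macrophages for cell cycle list -0.016 (from 0.27). Other values moved outside their interval in AN-GelMA over GelMA macrophages for inflammatory list 0.59 (from 0.88). With members passing the leak filter, called signs turned in AN-GelMA over GelMA fibroblasts for contractile list -0.25 (from 0.42), in GelMA over untreated fibroblasts for contractile list 0.28 (from -0.42), in AN-GelMA over GelMA keratinocytes for immediate early list -0.31 (from 0.22), in AN-GelMA over untreated keratinocytes for immediate early list -0.13 (from 0.26) and in AN-GelMA over untreated macrophages for immediate early list -0.37 (from 0.57). Moves outside the interval were seen in GelMA over untreated endothelial cells for sprouting list -0.31 (from -0.48), in AN-GelMA over GelMA keratinocytes for wound activation list -0.29 (from -0.097), in AN-GelMA over GelMA macrophages for inflammatory list 0.14 (from 0.88) and angiogenic list 0.85 (from 0.30), in AN-GelMA over untreated macrophages for inflammatory list 0.021 (from 0.51) and in GelMA over untreated macrophages for angiogenic list -1.04 (from -0.27). The last 3 alternatives differ by construction in which genes they hold.

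The next alternatives were added later and use other sets of cells by construction. Gene values in a single macrophage cluster are given without an interval, and some rest on few UMIs. Cxcl1 had 3 UMIs and Mmp9 17 in GelMA macrophages of all clusters together. In the Cd163 and Mrc1 cluster alone, called signs turned in AN-GelMA over GelMA macrophages for Cd36 -0.11 (from 1.21), Cxcl1 -2.88 (from 2.38), Mmp13 -1.29 (from 2.48), Mmp9 0.71 (from -1.57), Tnf 1.29 (from -0.95), Vegfa -1.29 (from 1.09), angiogenic list -0.084 (from 0.30) and mature list 0.0084 (from -0.30), in AN-GelMA over untreated macrophages for Ccl4 -0.30 (from 0.99), Ier2 -0.015 (from 1.21), Ptgs2 -0.72 (from 1.04), Wfs1 0.28 (from -1.31) and mature list -0.021 (from 0.36) and in GelMA over untreated macrophages for Birc5 -1.24 (from 0.69), Ccr2 -0.12 (from 0.90), Cdk1 -0.43 (from 1.10), Ciita -0.17 (from 1.18), H2-Eb1 -0.31 (from 0.60), Hsph1 1.40 (from -0.94), Ifit2 -0.43 (from 0.91), Ifit3 -0.69 (from 0.99), Il10 -0.17 (from 0.70), Mfge8 0.40 (from -1.74), Rrm2 -0.014 (from 1.93), Tnf -0.014 (from 1.05), Top2a -1.49 (from 0.83), Vegfa 0.57 (from -1.55) and interferon list -0.44 (from 0.59). Further moves were seen in GelMA over untreated macrophages for inflammatory list -0.098 (from -0.51) and angiogenic list -0.11 (from -0.27). In the Mmp12 and Spp1 cluster alone, called signs turned in AN-GelMA over GelMA macrophages for Arg1 -0.17 (from 1.03), Cd74 1.26 (from -0.72), Ciita 0.70 (from -0.86), H2-DMa 0.14 (from -0.88), Mgl2 0.52 (from -1.61), MHC class II list 0.91 (from -0.72), glycolysis list -0.0011 (from 0.60) and mature list 0.032 (from -0.30), in AN-GelMA over untreated macrophages for Lyve1 -0.27 (from 0.82), Ms4a4c -0.85 (from 1.06) and cell cycle list -0.088 (from 0.27) and in GelMA over untreated macrophages for Birc5 -0.47 (from 0.69), Cd74 -1.33 (from 0.85), Ciita -0.053 (from 1.18), H2-Eb1 -0.23 (from 0.60), Jun 0.099 (from -0.67), Mgl2 -0.053 (from 1.53), MHC class II list -0.91 (from 0.60) and immediate early list 0.38 (from -0.60). Outside their interval, with no call turned, were values in AN-GelMA over GelMA macrophages for angiogenic list 0.052 (from 0.30) and in GelMA over untreated macrophages for inflammatory list -0.0029 (from -0.51). Without the Nos2 cluster, called signs turned in AN-GelMA over untreated fibroblasts for Cxcl1 -0.055 (from 1.13), Nos2 1.01 (from -0.77) and glycolysis list 0.050 (from -0.37) and in GelMA over untreated fibroblasts for Ptgs2 0.098 (from -2.68). With hair-forming clusters counted as keratinocytes, called signs turned in GelMA over untreated keratinocytes for cell cycle list 0.23 (from -0.25). Other values moved outside their interval in AN-GelMA over GelMA keratinocytes for wound activation list 0.18 (from -0.097) and in GelMA over untreated keratinocytes for wound activation list -0.16 (from 0.16). Without the hair shaft and outer sheath clusters, called signs turned in AN-GelMA over GelMA keratinocytes for Tnc 0.50 (from -1.24) and immediate early list -0.076 (from 0.22) and in AN-GelMA over untreated keratinocytes for Krtap5-2 0.24 (from -6.41). Moves outside the interval were seen in AN-GelMA over GelMA keratinocytes for wound activation list -0.34 (from -0.097) and in GelMA over untreated keratinocytes for wound activation list 0.33 (from 0.16). Without hair-forming, unnamed, muscle and pigment cells, fibroblasts were 23.6% (from 22.2%) in AN-GelMA, 9.72% (from 6.07%) in GelMA and 21.3% (from 18.5%) in the untreated library, macrophages were 17.9% (from 16.9%) in AN-GelMA, 5.84% (from 3.65%) in GelMA and 13.1% (from 11.4%) in the untreated library and neutrophils were 1.42% (from 0.889%) in GelMA. With clusters under 50 cells named too, neutrophils were 0.961% (from 0.682%) in the untreated library.

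Depth limits the small classes most. In neutrophils 1 UMI is 8.17 CPM in GelMA and 10.4 in AN-GelMA, and the bound of 3 UMIs in GelMA macrophages is 8.57 CPM, so low cytokine genes there rest on few counts.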

Other observations

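No test beyond those above was added for this part, and its values were chosen after the data were seen. The hair-forming cells carried RNA of dividing and differentiating hair. Mki67, a gene of dividing cells, was at 153, 126 and 491 CPM in the hair-forming clusters of the untreated, GelMA and AN-GelMA libraries, and Top2a at 693, 259.9 and 673. Lef1, a Wnt pathway factor of the hair matrix, was at 944, 798 and 691, the cortex keratin Krt35 at 982, 1075 and 236, and the inner root sheath keratin Krt71 at 2462, 4592 and 273. In the outer root sheath type cluster Top2a was at 823, 226 and 809. A cluster led by Corin, Alx4 and Rspo2, genes of the dermal papilla that instructs the follicle, held 0.437%, 0.636% and 0.143% of cells.

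A cluster led by H2-M5 and Cd207, the latter a lectin gene of Langerhans cells, held 1.84%, 1.03% and 0.891% of the untreated, GelMA and AN-GelMA cells and stayed without a class. Clusters led by scattered vomeronasal receptor, Duxf3 and Spin2 genes, which match no skin cell type in the marker sets, held 3.04%, 0.0655% and 1.20%. Skeletal muscle cells per fibroblast were 0.164, 1.25 and 0.0821, and fibroblasts per blood endothelial cell 2.71, 1.53 and 5.68.

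Interferon genes in AN-GelMA over GelMA macrophages had a median of -0.22 [-0.30 to 0.095] over all macrophage clusters, but 0.62 [0.23 to 0.81] in the Cd163 and Mrc1 cluster and 0.46 [0.14 to 0.85] in the Mmp12 and Spp1 cluster. The monocyte list showed 0.14 [-0.35 to 0.73] over all, 0.98 [0.27 to 1.73] and 0.27 [-0.28 to 0.63]. Interferon genes were also above the random range in fibroblasts (0.45), keratinocytes (0.33) and neutrophils (1.55) of the same comparison, and not in endothelial cells (-0.24). Of these calls, that of keratinocytes ended without the hair shaft and outer sheath clusters (0.15 [0.038 to 0.29]) and that of neutrophils with thinned cells (1.09 [0.32 to 2.81]). Spp1, high in the Mmp12 macrophage cluster, was at 3080.1 CPM in GelMA neutrophils and 520.3 in AN-GelMA neutrophils, against 99.9 and 530.0 in macrophages.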
